A study of Mus musculus with 8 samples.

How the data were processed

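Whole liver RNA was sequenced in 8 samples from male mice, 4 controls with wild-type genotype and 4 HSC-PCK1-KO samples, in which Pck1 was knocked out in hepatic stellate cells, the vitamin A storing cells that turn into collagen-producing myofibroblasts in injured liver. Per the labels, all mice ate a choline-deficient high-fat diet (CDHFD), which produces fatty liver with inflammation and fibrosis, for 8 weeks, and all libraries belong to a single batch. Per the labels' protocols, livers were snap-frozen, RNA with an integrity number of at least 8 was used, mRNA was captured with oligo(dT) beads, and strand-specific paired-end reads of 100 bases were made on a DNBSEQ instrument.

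The authors deposited raw counts per gene, a whole number for each of 56953 gene identifiers in each library, with no normalization. Per the submitters' processing notes, the genome build was GRCm39 and R version 4.3.2 was used. The aligner, the counting tool, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Gene symbols were taken by identifier from GENCODE M21, an annotation of the earlier build GRCm38, which named 52029 of the identifiers. No coordinates are given, because the builds differ.

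Counts were analysed in R 4.3.3. Genes with too few counts were left out with edgeR's filterByExpr, which kept 15669 of the 28811 genes with any count. Libraries were scaled with TMM factors. The comparison of HSC-PCK1-KO with control used edgeR 4.0.16 (quasi-likelihood F-test with robust dispersion, genotype as the only term) on the counts as deposited, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Expression levels are in CPM, counts scaled by library total and TMM factor, and are given as mean ± SD over the 4 libraries of a group. A log2 fold change is HSC-PCK1-KO minus control, with its standard error (SE). Log2 CPM used a prior count of 2.

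47 gene lists, drawn from the study's title and from liver biology, were fixed before the data were examined. 960 of their 961 symbols were found in the annotation. Lists were tested with camera in limma 3.58.1 on voom log2 CPM with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the data and with fry. For each list the members were also adjusted over the list alone. A list score per library is the mean z score of log2 CPM over its members, and groups of scores were compared with an exact two-sided permutation test. With 4 libraries against 4 there are 70 assignments and the smallest p such a test can give is 0.0286.

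Genes were named by a rule fixed before the data were examined. It took Pck1 and Pck2, then, as no gene passed, the 10 genes with the smallest p in each direction with a mean of at least 1 CPM, leaving out predicted genes. It added the 4 members with the smallest p in each list past the threshold and in each list of the study's themes, and 8 readouts of fibrosis, glycolysis and the tricarboxylic acid (TCA) cycle. Some genes that the rule took are not reported here. Any other gene named was chosen after its values were seen.

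Alternatives were RLE and upper quartile factors, no filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with sample weights, the replicate number as a block, 1 surrogate variable from sva 3.50.0, an adjusted p of 0.1, a minimum log2 fold change of 1, and leaving out each library in turn. The calculations were tested on simulated data with the genes, means and dispersions of this comparison. Over 10 simulated sets of 15669 genes, 4.4% of genes changed 1.25-fold were recovered, 43.8% of those changed 1.5-fold, 81.4% of those changed 2-fold and 96% of those changed 3-fold, and 6.55% of calls were false. Each set held 200 changed genes, 50 at each fold. Recovery after adjustment depends on that number and can be lower where fewer genes change, which was not simulated. The changed genes were drawn only from those with a mean of at least 1 CPM, so recovery below that level was not measured. Each gene was simulated independently, without the correlation between genes of the real data.

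Library totals ranged from 44695439 to 49477255 counts. The median SE of a log2 fold change was 0.13 over all tested genes, and the 95% interval of a median gene reached 1.22-fold to either side. The median SE was 0.088 for the 6453 genes with a mean of 10 to 100 CPM and 0.33 for the 3106 genes under 1 CPM. The titles give every library a number of its own, but no label states that each came from a separate mouse, so p-values measure the spread between these samples. Pairs of libraries within a group differed by far more than counting noise, with a chi-square per degree of freedom from 48.7 to 184.9, so none was a copy of another.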

Results

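The data are gene counts from 8 liver samples of male mice fed a choline-deficient high-fat diet for 8 weeks, 4 control and 4 HSC-PCK1-KO. Totals per library ranged from 44695439 to 49477255 counts. The study's title places the loss of PCK1, the cytosolic enzyme that turns oxaloacetate into phosphoenolpyruvate, in hepatic stellate cells and links it to liver fibrosis, the TCA cycle and glycolysis. The comparison of the 2 genotypes therefore asks whether whole-liver transcripts of these themes differ.

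Pck1 (ENSMUSG00000027513.12), the targeted gene, stood at 1148 ± 616 CPM in control livers and 669 ± 264 CPM in HSC-PCK1-KO livers (SD, n = 4 each). The 4 control libraries had 1002, 2012, 551 and 1028 CPM, and the 4 HSC-PCK1-KO libraries had 339, 795, 593 and 948 CPM. The groups overlapped, with a log2 fold change of -0.78 (SE 0.44) and an adjusted p of 0.9998 in edgeR's quasi-likelihood test. Without control replicate 2 the log2 fold change was -0.36. Hepatocytes express Pck1 strongly, so its level in whole liver does not check a deletion in stellate cells. Pck2, the mitochondrial form of the enzyme, stood at 5.57 ± 0.98 CPM in control and 5.40 ± 1.03 CPM in HSC-PCK1-KO livers (SD, n = 4).

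The libraries did not separate by genotype on the leading components. Correlations of log2 CPM were 0.976 to 0.990 within groups and 0.979 to 0.991 between groups. The first principal component of the 500 most variable genes held 47.5% of the variance, and both genotypes spread along it. The second held 17.5%, with an exact permutation p of 0.714 for a difference between genotypes. The fourth, with 7.84% of the variance, parted the genotypes completely, at an exact permutation p of 0.0286.

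**Figure D1:**
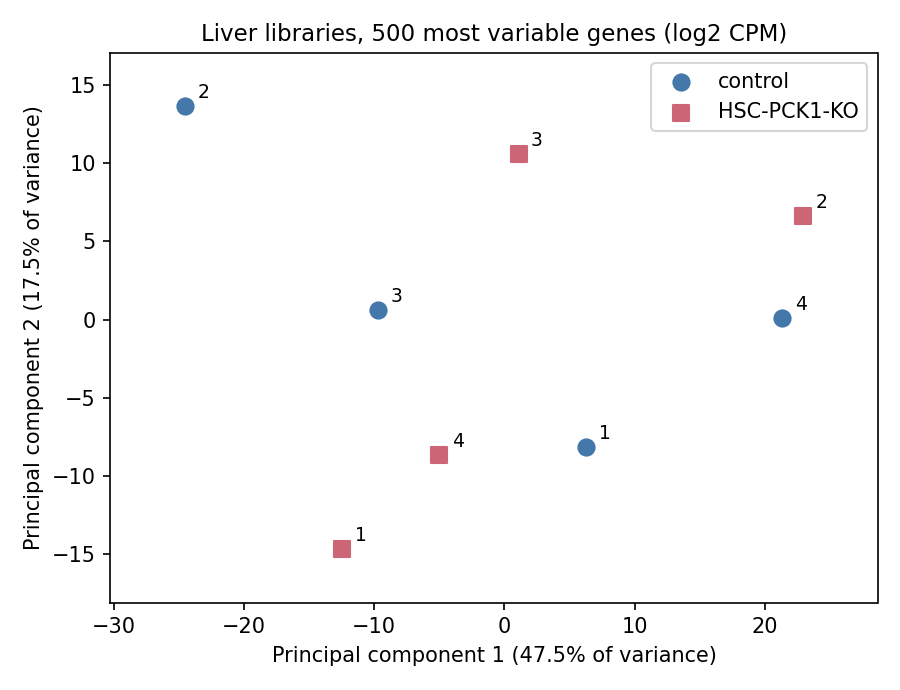
Each point is a liver library placed by its first and second principal component scores over the 500 most variable genes (log2 CPM), circles for control and squares for HSC-PCK1-KO, with replicate numbers. The genotypes intermix on both axes, which hold 47.5% and 17.5% of the variance.

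No gene passed an adjusted p of 0.05 between HSC-PCK1-KO and control in edgeR's quasi-likelihood test, 0 higher and 0 lower of 15669 tested. At an unadjusted p under 0.05 there were 370 genes, 160 higher and 210 lower, where chance gives 783.4. DESeq2 called 3 genes, Cobl and Upk3b lower and Blvrb higher, with 422 genes at an unadjusted p under 0.05. limma-voom with sample weights called 0, with 384 genes at an unadjusted p under 0.05. In 240 genes (1.53%) the groups did not overlap, against 2.86% by chance.

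Of the genes named for the smallest p, only Upk3b differed by over 2-fold, and none of them passed in edgeR. Among those lower in HSC-PCK1-KO, Cobl, an actin nucleator, stood at 14.2 ± 1.04 CPM against 19.9 ± 0.66 CPM in control (SD, n = 4), a log2 fold change of -0.48 (SE 0.073) with edgeR's adjusted p of 0.868. Ltbp4, a matrix protein that binds latent TGF-beta, stood at 40.4 ± 4.08 against 53.6 ± 5.97 CPM. Upk3b, a mesothelial gene, had the log2 fold change of these farthest from 0, standing at 0.98 ± 0.21 against 3.37 ± 1.68 CPM. Etfbkmt, Ulk2, Kitl, Zfp809, Ciart and Fmn1 were also on this side, with log2 fold changes from -0.99 for Ciart to -0.37 for Ulk2. On the other side, Blvrb, which encodes biliverdin reductase B, stood at 100.8 ± 9.67 CPM in HSC-PCK1-KO and 75.3 ± 3.63 CPM in control livers, and Krt23, a keratin, at 3.48 ± 0.90 and 1.78 ± 0.61 CPM. Ddt, Rasgrp2, Zc3h11a, Tvp23b, Dnajc12, Mif4gd and Selenow had log2 fold changes from 0.26 for Ddt to 0.53 for Zc3h11a.

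Collagen and other matrix genes were not higher in HSC-PCK1-KO livers. Of 34 extracellular matrix and collagen genes tested, 32 had a negative log2 fold change, with a median of -0.24, and the list was lower by camera (adjusted p = 6.98e-09). The call was lost with the estimated correlation of 0.639 in place of 0.01 (adjusted p = 0.992), and the list score differed with an exact permutation p of 0.314. The median was -0.081 without control replicate 4 (camera adjusted p = 0.019) and -0.15 without HSC-PCK1-KO replicate 1 (camera adjusted p = 0.00222), and the list score of the latter library, -1.30, stood apart from -0.14 to 0.065 in the other 3. In a relation chosen after the data were seen, recruited macrophage genes moved with the matrix genes across the 8 libraries (Pearson's r = 0.871, exact permutation p = 0.00841, adjusted p = 0.0252 over 6 relations, and Spearman's rho = 0.905, exact permutation p = 0.00456). Spp1 and Mmp12, members of the macrophage list, were left out of it for that relation. None of the 34 genes passed over all genes or adjusted over the list alone, and for all 34 the 95% interval excluded a 2-fold rise. For 28 it excluded a 1.5-fold rise, Col1a1 not being among them, and for 25 it excluded a 2-fold fall. Col1a1, the main chain of type I collagen, stood at 17.3 ± 6.76 CPM in HSC-PCK1-KO and 24.9 ± 13.6 CPM in control livers (SD, n = 4), a log2 fold change of -0.53 with a 95% interval from -1.66 to 0.61. It was -0.14 without control replicate 4 and -0.29 without HSC-PCK1-KO replicate 1. Col3a1 stood at 46.7 ± 14.2 and 55.7 ± 24.0 CPM. The 4 members with the smallest p were Lamb1, Col4a2, Col5a1 and Col6a2, with log2 fold changes of -0.42, -0.41, -0.36 and -0.71. Acta2, the smooth muscle actin of activated stellate cells, stood at 3.82 ± 0.47 and 3.45 ± 1.58 CPM, and Timp1, an inhibitor of matrix proteases, at 0.948 ± 0.39 and 1.24 ± 1.31 CPM. Matrix turnover genes were negative in 14 of 16 (camera adjusted p = 0.128), with Mmp9, Ctsk, Timp2 and Adamts2 at -0.70, -0.49, -0.27 and -0.33. They were lower by camera without control replicate 2 (adjusted p = 0.00127) or control replicate 3 (adjusted p = 0.0134) and turned direction without control replicate 4 (adjusted p = 0.588). TGF-beta signalling genes were negative in 13 of 20 (camera adjusted p = 0.736), with Tgfbr2 at -0.22, Bambi at 0.33, Bmp7 at 0.42 and Tgfb3 at -0.37.

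Glycolysis genes did not pass as a list, and 19 of 27 had a negative log2 fold change, with a median of -0.068 (camera adjusted p = 0.128). For all 27 the 95% interval excluded a 2-fold rise, and for 25 it excluded a 1.5-fold rise. Ldha, which makes lactate, stood at 1068 ± 124 CPM in HSC-PCK1-KO and 1027 ± 74.5 CPM in control livers (SD, n = 4). Pkm, the pyruvate kinase of non-parenchymal cells, stood at 18.8 ± 1.93 and 23.3 ± 5.63 CPM, and Hk2, a hexokinase, at 1.85 ± 0.25 and 2.03 ± 1.01 CPM. Aldoc, Pfkfb3 and Pklr had log2 fold changes of -0.49, -0.34 and -0.33, that of Pklr being -0.17 without control replicate 1, and none passed. The list was lower by camera without control replicate 2 (adjusted p = 0.0154) and turned direction without control replicate 1 (adjusted p = 0.996, median -0.019). Without control replicate 4 its median was 0.003, with 13 of 27 negative.

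TCA cycle genes were spread around 0, 18 positive and 15 negative of 33, with a median log2 fold change of 0.0063 (camera adjusted p = 0.425). The 95% interval excluded a 2-fold rise for 32 of the 33. Cs, citrate synthase, stood at 197.6 ± 9.95 CPM in HSC-PCK1-KO and 202.8 ± 23.9 CPM in control livers (SD, n = 4). Idh2, Sucla2 and Pdha1 had log2 fold changes of 0.19, 0.095 and 0.13. Gluconeogenesis genes, to which Pck1 belongs, were negative in 9 of 13 (camera adjusted p = 0.118), with G6pc at -0.54, Tat at -0.39 and Gpt2 at -0.12. That list was lower by camera without control replicate 4 (adjusted p = 0.0123) or HSC-PCK1-KO replicate 3 (adjusted p = 0.024). Its median of -0.082 was -0.027 without control replicate 2 (camera adjusted p = 0.541), where G6pc was at -0.28 and Tat at -0.10. Glutamine and anaplerosis genes were positive in 7 of 13 (camera adjusted p = 0.987). Asns, asparagine synthetase, had 4.88 ± 4.46 CPM in HSC-PCK1-KO and 2.00 ± 1.49 CPM in control livers, with 11.2 CPM in HSC-PCK1-KO replicate 3 and 4.22 CPM in control replicate 2. Its log2 fold change of 1.29 was 0.48 without HSC-PCK1-KO replicate 3. Slc38a3 and Slc38a2 had log2 fold changes of -0.24 and -0.20. Without control replicate 1 the TCA cycle list was higher by camera (adjusted p = 0.0233), and without control replicate 4 its direction turned (adjusted p = 0.931).

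**Figure D2:**
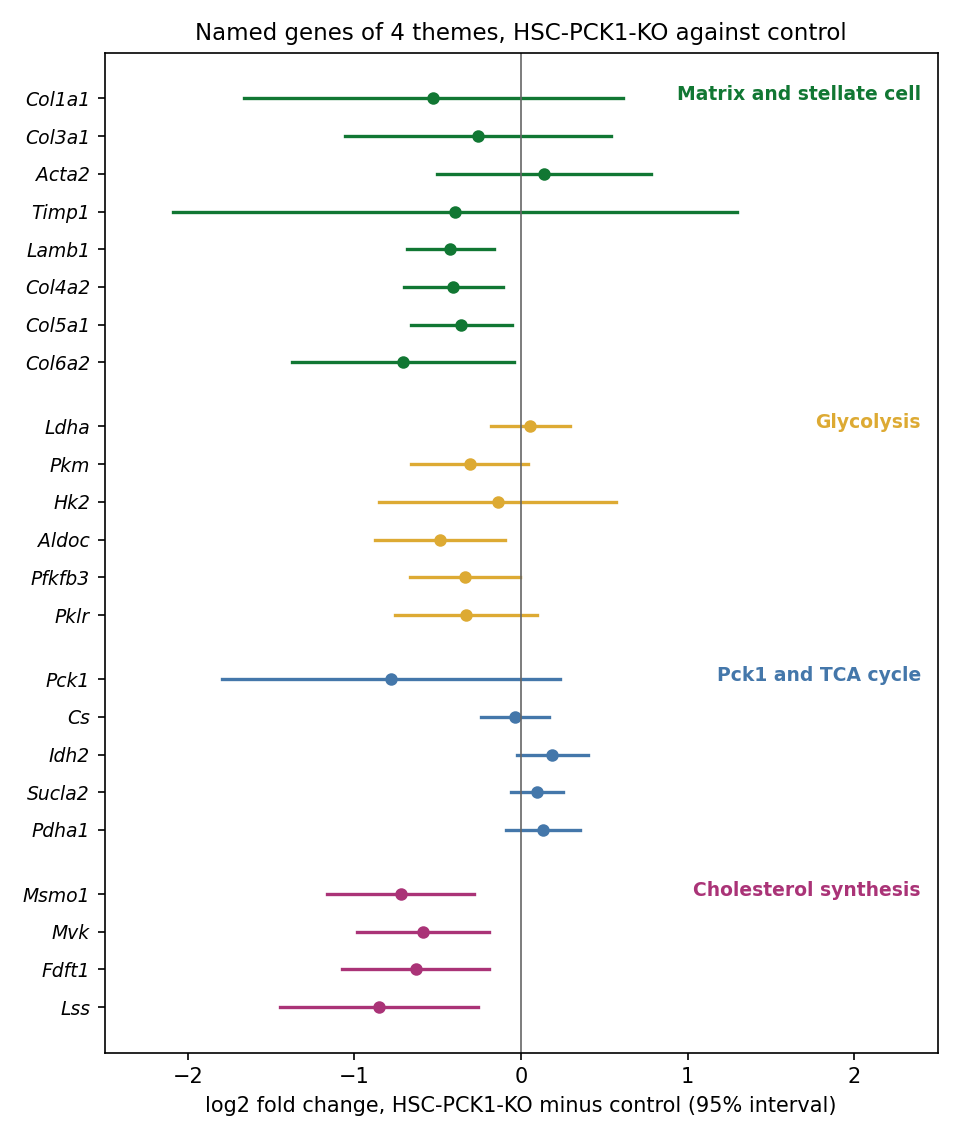
The log2 fold change of named genes of 4 themes, HSC-PCK1-KO minus control, is shown as a point with its 95% interval as a line (edgeR, n = 4 per group). The intervals of Col1a1, Col3a1, Acta2, Timp1, Ldha, Pkm, Hk2, Pklr, Pck1, Cs, Idh2, Sucla2 and Pdha1 span 0. Those of Lamb1, Col4a2, Col5a1, Col6a2, Aldoc, Pfkfb3, Msmo1, Mvk, Fdft1 and Lss lie below 0. The genes with intervals below 0 were named for having the smallest p in their lists. No gene passed after adjustment over all genes.

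Cholesterol synthesis genes were lower in HSC-PCK1-KO livers as a list. All 23 tested had a negative log2 fold change, with a median of -0.63, and 19 had an unadjusted p under 0.05 (camera adjusted p = 3.06e-28). With an estimated correlation the call was lost (adjusted p = 0.562). None of the 23 passed over all genes, and 11 passed adjusted over the list alone. Msmo1, a sterol methyl oxidase, stood at 166.3 ± 38.5 CPM in HSC-PCK1-KO and 274.4 ± 60.3 CPM in control livers (SD, n = 4), and Lss, lanosterol synthase, at 48.6 ± 12.8 and 87.7 ± 27.3 CPM. Mvk and Fdft1 had log2 fold changes of -0.59 and -0.63. Srebf2, which encodes the pathway's main transcription factor and was chosen after its values were seen, had 60.5 ± 7.92 and 74.2 ± 4.94 CPM. The groups did not overlap in 8 of the 23 genes, and overlapped in Msmo1, Mvk and Fdft1. List scores were 1.47, 0.73, 0.085 and 0.20 in control replicates 1 to 4. They were -1.54, -0.12, -0.054 and -0.77 in HSC-PCK1-KO replicates 1 to 4. Every control library thus had a higher list score than every HSC-PCK1-KO library, in part by a narrow margin. The exact permutation p was 0.0286, the smallest 4 against 4 can give. The list was the only 1 of 47 to reach that p, where 1.34 lists would by chance. The count of 11 was 0 without control replicate 1, control replicate 2 or HSC-PCK1-KO replicate 4, 1 without control replicate 4, 6 without HSC-PCK1-KO replicate 1 and 19 without HSC-PCK1-KO replicate 2.

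Fatty acid synthesis genes were negative in 20 of 21, with a median log2 fold change of -0.37 (camera adjusted p = 8.47e-06, and adjusted p = 0.992 with an estimated correlation). Acly, which supplies cytosolic acetyl-CoA, stood at 284.8 ± 56.9 CPM in HSC-PCK1-KO and 437.4 ± 143 CPM in control livers (SD, n = 4). Acss2, Lpin1 and Pnpla3 had log2 fold changes of -0.66, -0.64 and -1.82, that of Pnpla3 being -0.62 without control replicate 1. None passed adjusted over the list alone, and without control replicate 1 only 13 of 21 were negative, with a median of -0.105, and the list did not pass (camera adjusted p = 0.131). Fatty acid oxidation genes were positive in 22 of 28, with a median of 0.082 (camera adjusted p = 0.0199, and adjusted p = 0.992 with an estimated correlation). Bdh1, Acot1, Acadm and Acadl had log2 fold changes of 0.20, 0.40, 0.18 and 0.15. Without control replicate 2, control replicate 3, HSC-PCK1-KO replicate 1 or HSC-PCK1-KO replicate 2 the camera adjusted p was 0.284, 0.165, 0.222 and 0.739, and the median 0.024, 0.068, 0.039 and 0.017.

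**Figure D3:**
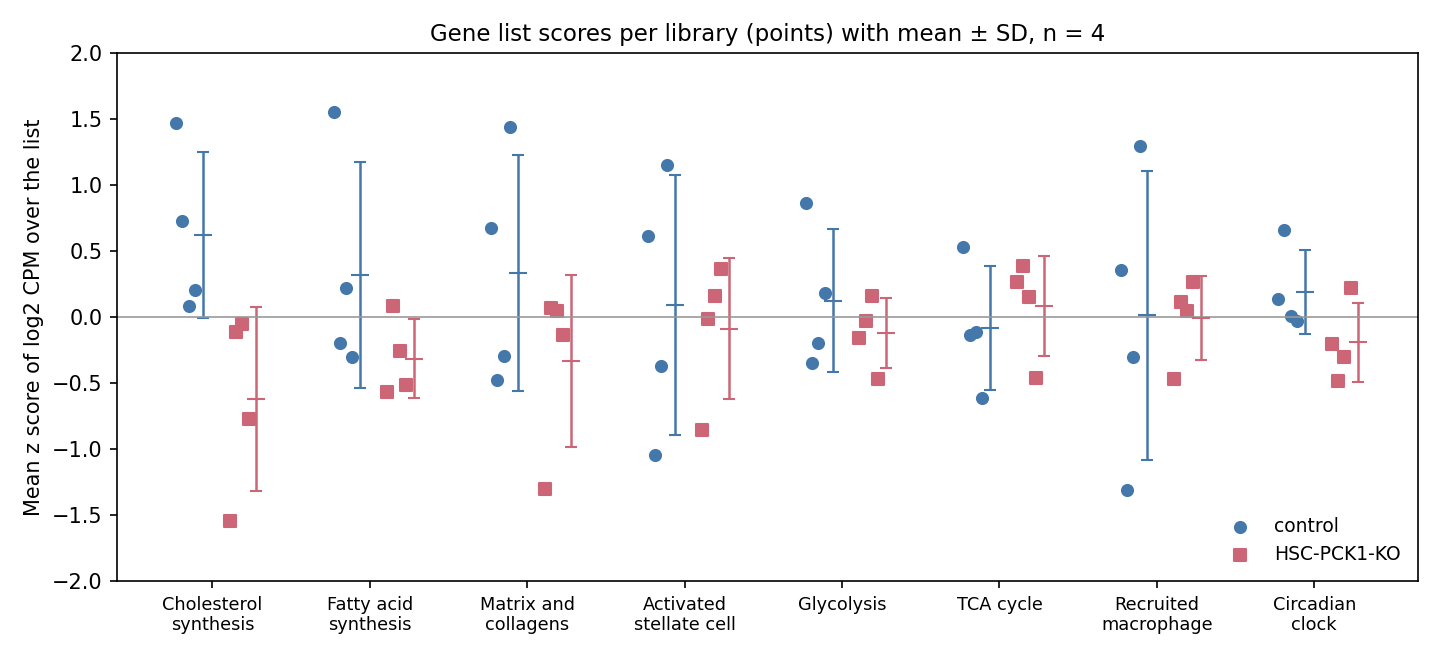
Scores of 8 gene lists per library (mean z score of log2 CPM over the list) are shown as circles for control and squares for HSC-PCK1-KO, with mean ± SD beside them (n = 4). The cholesterol synthesis scores of the genotypes do not overlap (exact permutation p = 0.0286), and those of the other 7 lists do.

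Circadian clock genes were negative in 11 of 19 and positive in 8, with a median log2 fold change of -0.088, and lower by camera (adjusted p = 0.0121, and adjusted p = 0.833 with an estimated correlation), and 2 of 19, Ciart and Per3, passed adjusted over the list alone. Ciart, a repressor within the clock, stood at 1.41 ± 0.33 CPM in HSC-PCK1-KO and 2.79 ± 0.72 CPM in control livers (SD, n = 4). Per3, Tef and Per2 had log2 fold changes of -0.50, -0.22 and -0.48. Without control replicate 2 or HSC-PCK1-KO replicate 2 the list did not pass (camera adjusted p = 0.142 and 0.0587), and the median ranged from -0.0245 without control replicate 2 to -0.213 without HSC-PCK1-KO replicate 4. NRF2 target genes of the oxidative stress response were positive in 18 of 24 (camera adjusted p = 0.0121, and adjusted p = 0.992 with an estimated correlation), with the glutathione transferases Gsta4 and Gsta2 at 0.31 and 0.25, Gclc at 0.25 and G6pdx at -0.42. Without control replicate 2, control replicate 3, HSC-PCK1-KO replicate 1 or HSC-PCK1-KO replicate 2 the adjusted p was 0.562, 0.12, 0.0632 and 0.152. The 13 mitochondrially encoded genes were positive in 12 (camera adjusted p = 0.0229, and adjusted p = 0.992 with an estimated correlation). The 4 members with the smallest p, mt-Atp8, mt-Co3, mt-Atp6 and mt-Co2, had log2 fold changes of 0.80, 0.55, 0.42 and 0.41, and their values are uncertain because mt-Co2, mt-Atp6 and mt-Co3 share at least 99.5% of their 100-base windows with nuclear transcripts and all 4 stood at no more than 13 CPM. Without HSC-PCK1-KO replicate 1 the adjusted p was 0.981 and the median 0.069 in place of 0.335, and without control replicate 1, control replicate 4 or HSC-PCK1-KO replicate 4 it was 0.08, 0.146 and 0.152. With a filter of at least 1 CPM in 4 libraries it was 0.108.

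Whether cell composition differed cannot be decided from scores of 12 cell-type marker lists. The smallest exact permutation p was 0.229, for B and plasma cells, but a list could pass adjustment over the 12 only if several sat together at 0.0286, the smallest exact p of 4 against 4. Activated stellate cell genes were negative in 13 of 18 (camera adjusted p = 0.399) and quiescent stellate cell genes in 12 of 16 (camera adjusted p = 0.182). The hepatocyte list had a median log2 fold change of -0.0066 and that of recruited macrophages -0.18. By camera, B and plasma cell genes were higher (adjusted p = 0.0121, and adjusted p = 0.992 with an estimated correlation), 12 of 15 being positive. Pax5, a B cell transcription factor, stood at 0.471 ± 0.15 CPM in HSC-PCK1-KO and 0.246 ± 0.042 CPM in control livers (SD, n = 4), and Cd79a, Blk and Ighd had log2 fold changes of 0.65, 0.43 and 0.36. That list did not pass without control replicate 2, control replicate 3 or HSC-PCK1-KO replicate 1 (camera adjusted p = 0.284, 0.182 and 0.0674, median 0.155, 0.143 and 0.072 in place of 0.324), nor with a filter of at least 1 CPM in 4 libraries (camera adjusted p = 0.171). A list of pancreas, gut, muscle and adipose markers was lower by camera (adjusted p = 0.0199, and adjusted p = 0.562 with an estimated correlation). Of its 6 tested genes only the mesothelial genes Upk3b and Msln passed adjusted over the list alone, while Cela2a and Vil1 had log2 fold changes of -0.15 and 0.17. Msln stood at 0.796 ± 0.25 CPM in HSC-PCK1-KO and 2.16 ± 0.95 CPM in control livers. That list did not pass without control replicate 2, HSC-PCK1-KO replicate 1 or HSC-PCK1-KO replicate 2 (camera adjusted p = 0.105, 0.0522 and 0.0608).

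In all, 9 of the 47 lists passed by camera, 5 lower and 4 higher, and none passed with an estimated correlation or with fry. Lists whose test, median and mean differed in sign all had a camera adjusted p of at least 0.869.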

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

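Of the tests here, the counts of genes and of lists over other splits were set before the result was seen, and those on cholesterol synthesis, mesothelial and mitochondrial genes were chosen only after it. Of the 35 splits of the 8 libraries into 4 and 4, the real one gave 0 genes and the highest other 22, and since every split gives at least 0 genes, that comparison decides nothing. All 35 gave at least as many lists as the real 9, up to 30 in another split, so chance cannot be excluded for the lists. 30 of the other splits had more genes at an unadjusted p under 0.05 than the real 370, and their median was 664.5.

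In 12 of 274 groups of 4 libraries, a library lay far from the other 3, where chance gives 13.7. Among genes these were Fmn1 in HSC-PCK1-KO replicate 1 at 4.56 CPM against 7.13 to 7.56 CPM, Col5a1 in that library at 9.05 against 12.2 to 12.7 CPM, Ighd in it at 2.14 against 1.34 to 1.41 CPM, and Cs in control replicate 1 at 238.4 against 187.3 to 193.2 CPM. Among list scores they were extracellular matrix in HSC-PCK1-KO replicate 1 at -1.30, acute phase response in control replicate 4 at 0.679, gluconeogenesis in HSC-PCK1-KO replicate 3 at 0.377, endoplasmic reticulum stress in the same library at 0.484, and glutamine and anaplerosis in control replicate 2 at 0.703. HSC-PCK1-KO replicate 2 had the highest total of its group, 49342122 counts against 47405693 to 47559785. HSC-PCK1-KO replicate 4 had 23114 genes with a count against 22615 to 22691, and control replicate 1 had a score on principal component 4 of 9.84 against 3.98 to 4.96.

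The cholesterol synthesis genes were lower in HSC-PCK1-KO, with a mean log2 fold change of -0.61. Of the 35 splits, 1, the real one, gave a mean as far from 0, the highest other being 0.577, but the list was picked out of 47 after the results were seen and 1.34 lists would reach its exact p by chance. A single library does not account for the direction, since at least 95.7% of the genes stayed negative whichever library was left out. As every control library scored above every HSC-PCK1-KO library, leaving out 1 could hardly turn the direction, so this adds little support. A different time of day of sampling stays open. The negative limb of the clock minus the positive limb, opposite in phase, was 1.491 in control and 0.868 in HSC-PCK1-KO livers on the log2 scale. The limbs thus stood closer in HSC-PCK1-KO, by -0.623 (95% interval -1.15 to -0.0977). But the limbs were set after the values of the clock genes had been seen, so this cannot support a different time of day. In a test added after that result and using the same limbs, a linear trend shared by both groups is argued against. Within groups the cholesterol score fell as the limb difference rose (slope -0.931, 95% interval -1.61 to -0.255). The genotype difference, -0.62 unadjusted, was -1.20 (95% interval -1.75 to -0.649) adjusted for the limb difference. Limb differences, 0.468 to 1.094 in HSC-PCK1-KO and 1.097 to 1.754 in control livers, do not overlap. The adjusted value is therefore an extrapolation and no estimate of the effect of the genotype. Fasting cannot be told apart, because 12 fasting-induced genes, Pck1 among them, differed by -0.0506 with a 95% interval from -0.509 to 0.408, and the genotype itself remains open and untested.

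The mesothelial genes Upk3b, Msln, Muc16, Lrrn4 and Igfbp6, picked out for their small p, were lower in HSC-PCK1-KO by a mean of -1.54 on the log2 scale, a value that no test on these same genes can support. Less liver capsule in the pieces taken is a candidate explanation. The mean of 10 other mesothelial markers differed by -0.779 (95% interval -1.72 to 0.161, exact permutation p = 0.143), so capsule content and genotype cannot be told apart. These 10 were listed after the values of a longer set had been looked at, and Krt7, Krt19 and Pdpn among them also belong to other lists, so they are no independent evidence. The most abundant of the 10, Gpm6a, stood at 1.44 ± 0.42 CPM in HSC-PCK1-KO and 1.98 ± 0.71 CPM in control livers (SD, n = 4).

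6 mitochondrially encoded genes, mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l, stood between 0.125 and 13 CPM in every library. A low level of the whole heavy-strand transcript is argued against, since the other 6 heavy-strand genes stood at no less than 4470 CPM in any library. Reads shared with nuclear copies and left uncounted are a candidate explanation for 5 of the 6, whose 100-base windows occur in nuclear transcripts of GENCODE M21 for at least 97.6%, against at most 60.8% for the other heavy-strand genes. For mt-Atp8 the share was 0 percent, and because nuclear sequence outside annotated transcripts was not searched, shared reads cannot be told apart there from other reasons. No other biological explanation was tested.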

How the results depend on the processing

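The fits named here were planned before the data were examined, and the counts of cholesterol synthesis genes under them were added after seeing the data. The count of 0 genes by edgeR (370 at an unadjusted p under 0.05) was also 0 with RLE or upper quartile factors, the stricter filter (279 unadjusted), no filter (686 unadjusted), limma-voom with sample weights (384 unadjusted), 1 surrogate variable (516 unadjusted), an adjusted p of 0.1 and a minimum log2 fold change of 1. DESeq2 (422 unadjusted) called 3. Leaving out each library gave 0 to 1, the 1 being Gm15920 without control replicate 1, with 248 to 502 unadjusted. The 9 lists by camera were 9 with RLE factors, 6 with the stricter filter, which ended the B and plasma cell and mitochondrially encoded calls (adjusted p = 0.171 and 0.108) and left too few genes of the pancreas list to test, 0 with an estimated correlation and 0 by fry. Leaving out each library gave 7 to 19 lists: 12, 19, 9 and 16 without control replicates 1 to 4, with 7, 4, 6 and 8 of the 9 among them, and 7, 8, 12 and 17 without HSC-PCK1-KO replicates 1 to 4, with 4, 5, 9 and 8 among them. The matrix list had an adjusted p of 0.992 with an estimated correlation and 0.977 by fry, and the cholesterol synthesis list 0.562 and 0.868. The cause was not tested.

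With the replicate number as a block the count of genes was 0 (311 unadjusted), and the lists by camera were 16, the 9 among them. With the block the glutamine list turned direction (adjusted p = 0.978) and matrix turnover passed (adjusted p = 0.0404). The numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.050, -0.61, 0.013 and -0.20, and 0 correlated best with their own number.

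Leaving out each library gave camera adjusted p from 0.0154 to 0.996 for glycolysis, 0.0233 to 0.931 for the TCA cycle, 0.00127 to 0.741 for matrix turnover, 0.125 to 0.843 for TGF-beta signalling and 0.35 to 0.903 for glutamine, each with a turn of direction, and 0.0123 to 0.541 for gluconeogenesis with none. It gave log2 fold changes that turned sign for 9 named genes: Acta2 -0.072 to 0.47, Cela2a -0.42 to 0.12, Col3a1 -0.43 to 0.056, Cs -0.073 to 0.050, Hk2 -0.33 to 0.17, Ldha -0.016 to 0.12, Pck2 -0.15 to 0.035, Timp1 -0.76 to 0.63 and Vil1 -0.18 to 0.48. In a count added after seeing the data, 41 of 82 named genes turned sign or shrank by over 1.5 times in log2 fold change with 1 library left out, such as Pkm to -0.14, Adamts2 to -0.043, Acly to -0.39, Cd79a to 0.34 and mt-Co2 to 0.13. Over the same leave-outs, medians ranged from -0.369 to -0.081 for matrix, -0.755 to -0.485 for cholesterol synthesis, -0.547 to -0.105 for fatty acid synthesis, 0.017 to 0.16 for fatty acid oxidation, 0.075 to 0.184 for NRF2 targets, 0.069 to 0.522 for mitochondrially encoded genes, 0.072 to 0.508 for B and plasma cells and -0.419 to -0.062 for the pancreas list. Among lists that did not pass these were -0.0138 to 0.0466 for the TCA cycle, -0.387 to 0.0513 for matrix turnover, -0.124 to 0.0143 for TGF-beta signalling and -0.0961 to 0.0279 for glutamine. With sample weights Cela2a was at 0.077 and Timp1 at 0.18, and with 1 surrogate variable Timp1 was at 0.025. Of 1352 values of named genes under alternatives, 1332 kept their sign and side of the threshold. As no named gene passed in edgeR, keeping that side says little about how stable the values are. The cholesterol synthesis genes past adjustment over the list alone, 11, were 20 with DESeq2, 18 with sample weights, 17 with upper quartile factors, 8 with the stricter filter, 12 without HSC-PCK1-KO replicate 3, 16 without control replicate 3, and 0 with no filter, the block or 1 surrogate variable; at least 22 of 23 were negative in each. Depth limits genes under 1 CPM, such as Muc16 and Cela2a.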

Other observations

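Other gene groups fixed before the data were examined did not pass by camera. Acute phase genes were positive in 17 of 24 (adjusted p = 0.051), pericentral hepatocyte genes in 9 of 15 (adjusted p = 0.0538), nuclear genes of oxidative phosphorylation in 24 of 36 (adjusted p = 0.118) and p53 target and apoptosis genes in 13 of 19 (adjusted p = 0.133). Interferon response genes were negative in 24 of 37 (adjusted p = 0.133), cell cycle genes in 24 of 38 (adjusted p = 0.556), hypoxia genes in 12 of 21 (adjusted p = 0.842) and growth factor signalling genes in 16 of 23 (adjusted p = 0.0895). Ribosomal protein genes had a median log2 fold change of 0.016 and all 30 had 95% intervals that excluded a 2-fold change in either direction. Choline and methionine metabolism genes, the diet's own target, had a median of 0.021 over 19 genes (adjusted p = 0.7).

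Across the 8 livers, whatever their genotype, mean log2 CPM of matrix genes followed that of recruited macrophage genes, a relation chosen after the data were seen and 1 of 6 computed. The macrophage score used here leaves out Spp1 and Mmp12, which the macrophage list score elsewhere includes. Pearson's r was 0.871 (exact permutation p = 0.00841, adjusted p = 0.0252) and Spearman's rho 0.905 (exact permutation p = 0.00456), with r = 0.825 without the 2 libraries farthest from the median. Matrix genes ran against hepatocyte genes, with r = -0.798 (exact permutation p = 0.0203, adjusted p = 0.0406), rho = -0.952 (exact permutation p = 0.00114) and r = -0.869 without those 2. Matrix genes against the 10 mesothelial markers had r = 0.879 (exact permutation p = 0.00756, adjusted p = 0.0252), rho = 0.690 (exact permutation p = 0.0694) and r = 0.605 without those 2, on which it rests in part. The relations of matrix genes with male-biased genes (r = -0.328, rho = -0.381), of matrix with cholesterol synthesis genes (r = 0.576, rho = 0.429) and of cholesterol synthesis genes with the clock limb difference (r = 0.187, rho = 0.571) had exact permutation p of 0.424 and 0.36, 0.126 and 0.299, and 0.674 and 0.151, and adjusted p of 0.509, 0.189 and 0.674 for r. Without the 2 farthest libraries r was -0.826, 0.334 and 0.409. The positive r with the clock limb difference does not hold within genotypes, where the common slope was -0.931 (95% interval -1.61 to -0.255). The macrophage score was 1.94 in control replicate 2 and 3.73 in control replicate 4 on the log2 scale, a wider span within the controls than between the group means of 2.86 and 2.86.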
